A study of Arabidopsis thaliana with 8 samples.

How the data were processed

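RNA was measured in 8 libraries of Arabidopsis thaliana Col-0 reproductive tissue, 4 wild type and 4 mutant in LSH1, LSH3 and LSH4. Per the labels, plants grew under 16 h light and 8 h dark at 20 to 22 °C, RNA came from a plant mini column kit, and libraries were made by a commercial provider after poly-A enrichment. Groups and replicate numbers were taken from the sample titles. The groups share no replicate number.

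The deposited expression table gives 1 FPKM value per gene and library (fragments scaled by gene length and library total), as named by the deposited file. Per the submitters' processing notes, RSEM and DESeq2 were used and the genome build was TAIR10, with no versions; the aligner, the annotation version and filters are not given in the sources used here. No read counts were used here, so no count model was fitted. FPKM divides out gene length and library total, so a few abundant genes can shift all others, and absolute depth is lost; relative depth was read from the steps between low values of genes present in at most 6 libraries, taking the commonest ratio to wild type replicate 1 where it led the next by 1.5 times in genes. The number of reads sets the counting error of low genes, and no counting interval could be given.

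The authors' deposited table of differential genes gives a log2 fold change of mutant against wild type, a p-value and an adjusted p-value per gene, per the file headers. It has 825 rows for 822 genes, since 3 genes are listed more than once, and its largest adjusted p-value is 0.0499. The ratio of adjusted to raw p-value in its leading row corresponds to about 20096 tested genes. That the authors' deposited table came from DESeq2 is presumed from its column names.

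Gene symbols were matched by AGI code to the RefSeq annotation of assembly TAIR10.1, in which 22154 of the 22281 codes were found and 127 were not. Since the authors' build is TAIR10, no coordinates are printed, and the annotation served only for names and for gene order.

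Here, log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3 (2 groups, moderated with a mean-variance trend, 2-sided) over 17706 genes with a mean FPKM of 1 or more, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The prior degrees of freedom were 2.67. Intervals are 95%. The median log2 fold change of all genes was -0.01. Over all genes tested, 2219 had an unadjusted p under 0.05 (1224 higher, 995 lower), and in 7.89% the genotypes did not overlap, where chance gives 2.86%.

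Before the data were examined, 25 gene lists of 319 genes were fixed, of which 250 were tested. They cover the ALOG family, organ boundary, shoot meristem, floral transition, floral organs, gynoecium, polarity, TCP class II, hormones, cell division, meiosis, stress and defence, flavonoids and the clock, and markers of green, stem, epidermal and later floral tissue. Each was tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera at an estimated correlation and with fry. A list's mean level is the mean log2(FPKM + 1) over its tested members in 1 library. Named genes followed a rule set at the same time: the 10 largest increases and the 10 largest decreases among genes past the threshold with no overlap between genotypes and a symbol (5 decreases met it), the 10 ALOG genes, and in each list the called members, at most 4, or otherwise the 2 with the smallest p. Other list members are given as values that bear on a group.

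The fitting code was tested on simulated data: in 10 runs over 17706 genes with the real means and spreads and 200 changed genes, 78.6% of genes changed by 1 log2 unit and 95.1% of those changed by 2 were recovered for mutant against wild type, and 5.44% of calls were false. Camera with the preset correlation called a list of raised genes in 10 of 10 runs and a list of unchanged genes in 2 (unadjusted p under 0.05). Noise was drawn independently for each gene, so these rates may not hold for real genes that vary together. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of 5, TPM rescaling, median-of-ratios and quantile scaling, robust moderation, library weights, stricter thresholds and leaving out each library. After the data were seen, the touch list mean and the photosynthesis list mean were each added as a covariate, and a threshold of 0.10 was tried. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.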

Results

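Poly-A RNA was sequenced from Arabidopsis thaliana reproductive tissue, enriched in inflorescence meristems, floral meristems and flowers up to stage 8. The series holds 8 libraries in the Col-0 background, 4 from wild type (replicates 1 to 4) and 4 from plants mutant in LSH1, LSH3 and LSH4 (replicates 5 to 8). These genes belong to the ALOG family of 10 genes, which encode plant-specific nuclear proteins. The comparison asks which transcripts differ in young inflorescences when 3 members of that family are mutated. The series calls the replicates independent, and the labels do not say whether each came from separate plants, so p-values measure the spread between these samples, which may be partly technical.

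Transcript levels were given as FPKM for 22281 genes, of which 17706 had a mean of 1 or more over the 8 libraries and were tested. Read totals were unknown. The FPKM sums ran from 826022 to 906962, which are not depths. Steps between low values gave the reads behind 1 FPKM relative to wild type replicate 1: 1.41 times in wild type replicate 2, 1.04 in replicate 3, 1.37 in replicate 4, 1.22 in mutant replicate 6 and 1.37 in mutant replicate 7. They were not settled for mutant replicates 5 and 8. Mutant replicate 8 listed the most genes at 0 (2461), against 1233 to 1884 in the other libraries. Across genes, which are not independent replicates, Spearman correlations were 0.940 to 0.989 within a genotype and 0.917 to 0.987 between genotypes. The first principal component held 43.0% of the variance and placed wild type replicates 1 and 2 at -55.0 and -24.2, wild type replicates 3 and 4 at -0.99 and 9.08, and the mutants between 2.67 and 39.0.

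LSH4 and LSH1 fell in the mutant, and LSH3 did not pass the test. LSH4 (AT3G23290) went from 22.1 ± 2.08 FPKM in wild type to 5.51 ± 1.42 in the mutant (mean ± SD, n = 4 each), a log2 fold change of -1.85 (SE 0.16, limma with Benjamini-Hochberg adjustment, adjusted p = 0.00773). LSH1 (AT5G28490) went from 10.1 ± 1.96 to 2.87 ± 0.97 FPKM (log2 fold change -1.53, SE 0.20, limma adjusted p = 0.0423). For both genes every mutant library lay below every wild-type library. LSH3 (AT2G31160) had 17.2 ± 5.28 FPKM in wild type and 13.5 ± 2.35 in the mutant, with overlapping libraries, a log2 fold change of -0.30 and a 95% interval from -0.80 to 0.21 (limma adjusted p = 0.607). Its transcript level therefore does not separate the genotypes, and the labels do not describe the alleles.

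**Figure D1:**
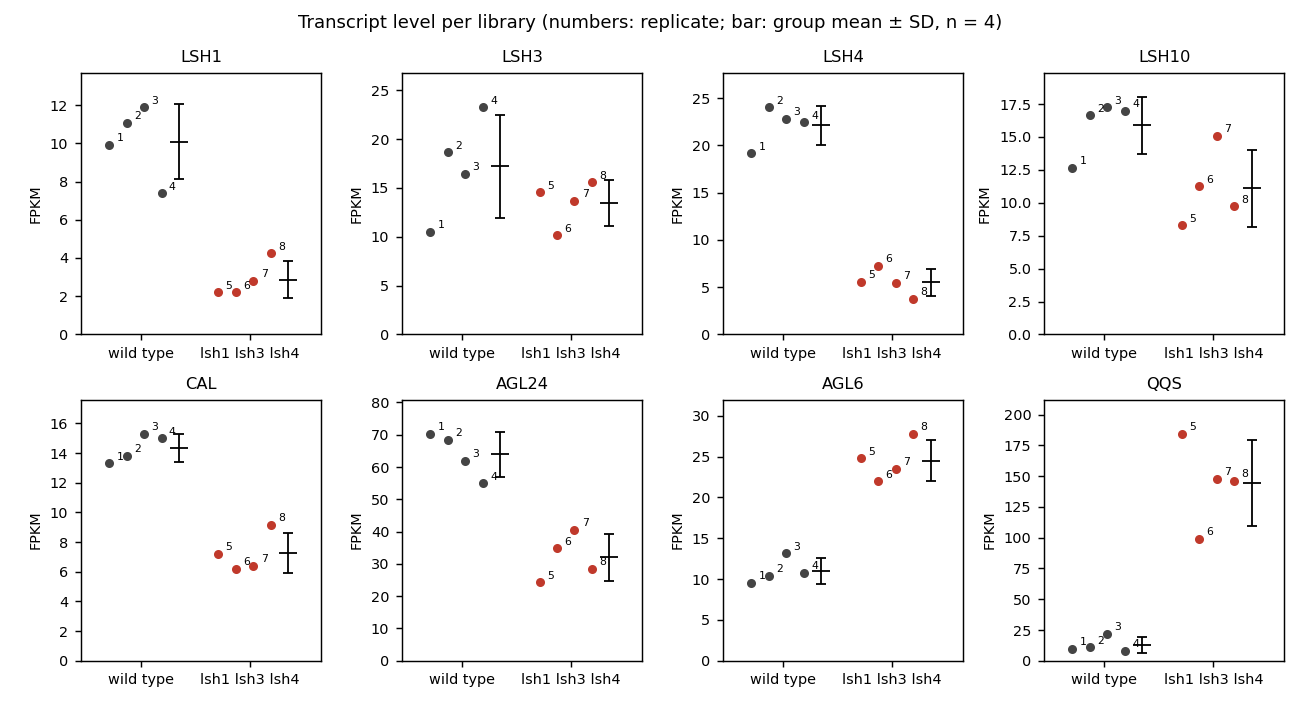
FPKM per library (vertical axes, from 0) for LSH1, LSH3, LSH4, LSH10, CAL, AGL24, AGL6 and QQS; points are single libraries with their replicate number, and bars show the group mean ± SD (n = 4). LSH4 lies between 3.79 and 7.25 FPKM in the mutants and between 19.2 and 24.04 in wild type, while the libraries of both genotypes overlap for LSH3 and LSH10.

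Among the rest of the ALOG family no gene passed the test over all genes. LSH10 (AT2G42610) had 15.9 ± 2.17 FPKM in wild type and 11.1 ± 2.93 in the mutant (log2 fold change -0.50, limma adjusted p = 0.295), and was the third member to pass when adjusted over the list alone (adjusted p = 0.0372). LSH5 (log2 fold change 0.16) and LSH6 (-0.03) passed neither test, and LSH2, LSH7, LSH8 and LSH9 had mean levels under 1 FPKM. Of 6 tested members, 2 fell over all genes, and 3 were lower when adjusted over the list alone. The count over the list alone was 2 without wild type replicate 2, 3 or 4 or without mutant replicate 5, 6 or 8. It was 4 without wild type replicate 1. The list of 6 was called lower (camera adjusted p = 0.00165, adjusted p = 0.242 with an estimated correlation). It was the 1 list of 25 called by fry's test for a shared direction (adjusted p = 0.00796). It includes the mutated genes LSH1, LSH3 and LSH4, so the call largely restates the decrease of LSH1 and LSH4 and says little about the other members.

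Over all genes 24 transcripts rose and 9 fell (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05), and in all 33 the genotypes did not overlap. The increases were led by QQS (AT3G30720), an orphan gene linked to starch and protein content, which went from 12.8 ± 6.32 to 144 ± 35.0 FPKM (log2 fold change 3.46, SE 0.29, adjusted p = 0.00773). Next among the increases with a symbol, the low-affinity sulfate transporter gene SULTR2;1 (AT5G10180) went from 0.79 ± 0.25 to 5.46 ± 1.06 FPKM (1.85, SE 0.17, adjusted p = 0.00971). A further 10 called increases have no symbol. They include AT4G19430, a larger increase (2.19, adjusted p = 0.0425) that was named after its values were seen. The nitrate transporter gene NRT1.5 (AT1G32450) went from 0.46 ± 0.11 to 3.61 ± 0.97 FPKM (1.63, SE 0.18, adjusted p = 0.0285). JAZ9 (AT1G70700), which encodes a repressor of jasmonate signalling, went from 52.4 ± 14.7 to 152 ± 30.2 FPKM (1.54, SE 0.21, adjusted p = 0.0425). Also among the 10 largest named increases were APT3 (1.33), the cellulose synthase-like gene CSLB04 (1.12), AGL6 (1.096), CDT1 (AT1G52827, a cadmium tolerance gene and not the replication factor of that name; 1.08), PP2-A14 (0.96) and the plasma membrane proton pump gene HA1 (0.85), which went from 123 ± 12.2 to 222 ± 19.5 FPKM.

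Besides LSH4 and LSH1, the decreases with a gene symbol were ERF15, PCK1 and CAL. ERF15 (AT2G31230), an ethylene response factor gene, went from 2.63 ± 0.54 to 0.54 ± 0.09 FPKM (log2 fold change -1.23, limma adjusted p = 0.0397). Its AGI code is close to that of LSH3 (AT2G31160), and a local effect of that locus was not tested. PCK1 (AT4G37870), encoding phosphoenolpyruvate carboxykinase of gluconeogenesis, went from 130 ± 26.8 to 55.2 ± 8.39 FPKM (-1.20, adjusted p = 0.0425). The other 4 decreases, AT3G46220 (-1.59), AT1G63630 (-1.55), AT2G26695 (-1.20) and AT3G48240 (-1.02), have no symbol and were named after their values were seen. These counts rest on all 8 libraries: leaving out wild type replicate 2 left 0 calls by limma (843 higher and 582 lower at an unadjusted p under 0.05), and leaving out wild type replicate 3 gave 79 increases and 25 decreases. LSH4, QQS and AT3G46220 each stayed past the threshold in 7 of the 8 fits that left out 1 library, SULTR2;1 in 5 and AGL6 in 4, CAL, LSH1, NRT1.5, HA1 and CDT1 in 2, JAZ9 in 0, and the other 5 named genes in 1.

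Of the floral transition and floral organ genes, CAL and AGL6 passed the test over all genes. CAL (AT1G26310), a floral meristem identity gene, fell from 14.4 ± 0.95 to 7.24 ± 1.35 FPKM (log2 fold change -0.91, SE 0.12, limma adjusted p = 0.0425). AGL6 (AT2G45650), which has roles in floral organs, rose from 11.0 ± 1.56 to 24.5 ± 2.48 FPKM (1.096, SE 0.11, adjusted p = 0.0179). Of 17 tested floral transition and floral meristem identity genes, 1 fell over all genes and 12 passed neither test. Adjusted over the list alone 4 were lower, namely CAL, AGL24 (-0.99, 63.9 ± 6.94 against 32.0 ± 7.20 FPKM), SVP (-0.56) and SPL15 (-0.51), and 1 was higher, the floral integrator SOC1 (0.43). When 1 library was left out 2 to 4 were lower and 0 to 2 higher. None was higher without wild type replicate 2 or 3 or without mutant replicate 5, 6 or 7. LFY (-0.14), AP1 (-0.56) and TFL1 (0.48) passed neither test. Members went both ways, and camera did not call the list as a whole (adjusted p = 0.134). Fry's test for change in either direction called it (adjusted p = 1.76e-06). With the touch list mean as a covariate camera called it lower (median -0.37, adjusted p = 0.00823). With the photosynthesis list mean as a covariate its median was 0.04.

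Of 11 tested floral organ identity genes, AGL6 was higher both over all genes and when adjusted over the list alone, and 10 passed neither test. AP3 (-0.21), PI (-0.20) and AG (-0.13) had negative values and SEP1 (0.61) and SEP4 (0.35) positive ones. The list was called higher (camera adjusted p = 0.0489, adjusted p = 0.666 with an estimated correlation). That call was lost at pseudocounts of 0.1 and 0.5, with no filter and after rescaling to TPM. It was also lost without wild type replicate 1 (median -0.02, adjusted p = 0.275) or 3 (0.0808), without mutant replicate 5 (0.0940) or 8 (median -0.10, adjusted p = 0.618), and with the touch list mean as a covariate (median -0.44, adjusted p = 0.563). The list's mean level ran from 3.36 to 4.46 log2 units in wild type and from 3.49 to 4.93 in the mutant. The 9 tested gynoecium and ovule genes included none that passed either test (camera adjusted p = 0.604; NGA2 had 0.90 and NGA3 0.53). That list was called higher without mutant replicate 6 (median 0.32, adjusted p = 0.00743), while its median was -0.18 without mutant replicate 8. None of the 15 organ polarity genes passed either (camera adjusted p = 0.604; YAB2 had 0.80 and KAN2 -0.43), nor did any of the 6 early anther and meiosis genes (camera adjusted p = 0.213; TPD1 had -0.48 and SPO11-1 -0.28).

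Organ boundary genes went in different directions. BOP1 (AT3G57130), a boundary gene of the BTB-ankyrin family, had 0.62 ± 0.28 FPKM in wild type and 3.01 ± 1.06 in the mutant (log2 fold change 1.29, SE 0.22). Its paralogue BOP2 had 5.12 ± 1.64 and 12.4 ± 4.87 FPKM (1.09, SE 0.29). The MYB gene LOF1 had 26.1 ± 3.09 and 19.2 ± 1.84 FPKM (-0.42, SE 0.10). Over all genes none of the 13 tested members passed (limma adjusted p = 0.0853 for BOP1, 0.185 for BOP2 and 0.165 for LOF1). Adjusted over the list alone 2 were higher (BOP1 and BOP2), 1 was lower (LOF1) and 10 did not pass, among them CUC1 (-0.35), CUC2 (-0.39) and CUC3 (-0.24). Only 1 was higher without wild type replicate 1 or 3 or without mutant replicate 5 or 8, and 0 were lower without mutant replicate 8. The list was not called (camera adjusted p = 0.799), its median was -0.14 and camera's direction was down, while its mean was 0.06. Fry's test for change in either direction called it (adjusted p = 0.00472). With the touch list mean as a covariate camera called it lower (median -0.38, adjusted p = 0.0328), and with the photosynthesis list mean its median was 0.04.

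Most meristem and cell division genes had small negative values. Of 8 tested shoot meristem genes none passed over all genes, and 6 had negative and 2 positive values (CLV1 0.08, KNAT2 0.01). Adjusted over the list alone 2 were lower: the homeobox genes STM (AT1G62360; 87.0 ± 9.41 against 66.7 ± 3.25 FPKM, log2 fold change -0.37) and BLR (AT5G02030; 37.5 ± 5.29 against 27.8 ± 2.202 FPKM, -0.41). The list was called lower (camera adjusted p = 0.0348, adjusted p = 0.527 with an estimated correlation) with a median of -0.13. That call was lost without wild type replicate 3 (adjusted p = 0.0591) or 4 (0.0861), without mutant replicate 7 (0.0507) or 8 (0.0675), and with the photosynthesis list mean as a covariate (median -0.05, adjusted p = 0.159). All 10 G2 and mitosis genes had negative values (median -0.18), none passed over all genes, and 2 were lower when adjusted over the list alone, CDKB2;2 (-0.30) and CDKB2;1 (-0.28), a count of 0 to 4 when 1 library was left out. That list was called lower (camera adjusted p = 0.00165, adjusted p = 0.527 with an estimated correlation), and with the photosynthesis list mean as a covariate its median was -0.05 and the call was lost (adjusted p = 0.619). All 6 DNA replication genes MCM2 to MCM7 had negative values without passing either test (MCM7 -0.23, MCM3 -0.19), and the list was not called (camera adjusted p = 0.159). It was called lower without wild type replicate 1 (median -0.26, adjusted p = 0.0115) and with the touch list mean as a covariate (median -0.48, adjusted p = 5.50e-06), where all 6 were lower when adjusted over the list alone.

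Markers of green and stem tissue had positive values, with no member past either test. All 20 photosynthesis genes, which mark green tissue, had positive values (median 0.46), none passed over all genes and 0 passed when adjusted over the list alone. The list was called higher (camera adjusted p = 1.21e-09, adjusted p = 0.527 with an estimated correlation). Its mean level was 9.77, 9.28, 10.2 and 9.24 log2 units in wild type replicates 1 to 4, against 10.03 to 10.40 in the mutants, so that wild type replicate 3 lay within the mutant range. RBCS2B (1.97) and LHCB4.2 (0.67) had the smallest p-values. The RBCS and LHCB1 genes are near-identical copies that may share reads, so their single values are uncertain. Without wild type replicate 3, 17 of the 20 genes were higher when adjusted over the list alone.

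All 9 vascular and stem genes also had positive values (median 0.25; IRX1 0.44, XCP2 0.41), with none passing either test (camera adjusted p = 0.0211, adjusted p = 0.527 with an estimated correlation). The call was lost without wild type replicate 4 (adjusted p = 0.148) and without mutant replicate 6 (0.1596) or 7 (0.0507), and with the photosynthesis list mean as a covariate (median -0.0024, adjusted p = 0.920). None of the 5 epidermis genes passed (camera adjusted p = 0.188; PDF2 had 0.33 and FDH 0.34). Of 17 tapetum and pollen wall genes, which mark flowers past stage 8, only LAP6 (0.11) and TKPR1 (-0.01) reached 1 FPKM, and neither passed (camera adjusted p = 0.765).

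Early stress genes were higher in some wild-type libraries. All 14 tested touch, wounding and early stress genes had negative values (median -1.96). None passed over all genes, and 10 were lower and 4 did not pass when adjusted over the list alone. That count moved in most fits that left out 1 library: 3 were lower without wild type replicate 2 or without mutant replicate 5, 6 or 7, and 4 without mutant replicate 8. It was 10 without wild type replicate 1, 9 without wild type replicate 3 and 12 without wild type replicate 4. The zinc finger gene ZAT12 (AT5G59820) had 35.9 ± 33.0 FPKM in wild type and 3.41 ± 1.90 in the mutant (log2 fold change -2.68), and the cold-response factor gene CBF2 (AT4G25470) had 4.43 ± 3.18 and 0.27 ± 0.14 FPKM (-1.87). Camera called the list lower (adjusted p = 5.12e-08, adjusted p = 0.527 with an estimated correlation). Its mean level was 6.05, 4.29, 3.40 and 2.29 log2 units in wild type replicates 1 to 4 and 1.87 to 2.39 in the mutants. Wild type replicate 1 held the highest value of all 14 genes, and replicate 4 lay within the mutant range. The 2-sided exact permutation p of the list mean was 0.0571, where 0.0286 is the smallest that 4 against 4 libraries allow.

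**Figure D2:**
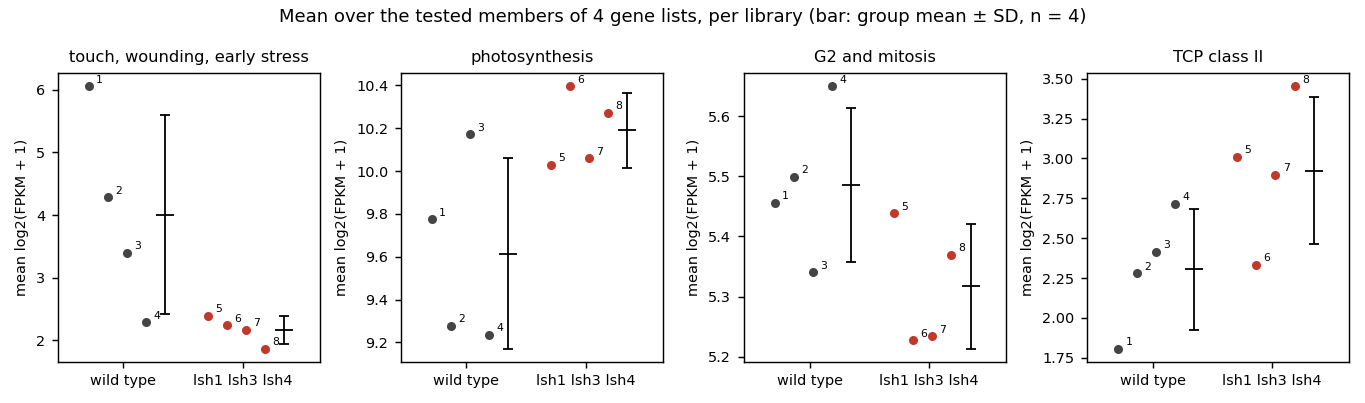
Mean log2(FPKM + 1) over the tested members of 4 gene lists (vertical axes, not starting at 0) in each library; points carry the replicate number, and bars show the group mean ± SD (n = 4). The touch list runs from 2.29 to 6.05 in wild type and from 1.87 to 2.39 in the mutant, and wild type replicate 3 (10.2) lies among the mutants for photosynthesis.

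Heat shock genes had negative values, in large part through wild type replicate 1. All 7 tested members had negative values (median -0.47; HSP17.4 -1.05, HSP17.6A -0.74) and none passed either test. The list was called lower (camera adjusted p = 0.0271, adjusted p = 0.527 with an estimated correlation), and its mean level was 4.45 in wild type replicate 1 against 2.41 to 3.14 in the other libraries. Without wild type replicate 1 the call was lost (adjusted p = 0.975, over the 5 members still past the FPKM minimum), as it was without mutant replicate 8 (0.0967). Over the same 7 members without wild type replicate 1, 4 had negative values and the median was -0.11. HSP17.6A stayed lower in every mutant library (0.387 to 0.768 FPKM) than in wild type replicates 2 to 4 (0.871 to 2.05 FPKM). None of the 7 salicylate-linked defence genes passed (camera adjusted p = 0.0979; SAG101 had -0.69 and NPR1 -0.45). Without wild type replicate 4 the defence list was called lower (adjusted p = 0.0240), and without wild type replicate 3, 4 of the 7 were lower when adjusted over the list alone.

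Jasmonate repressor genes had positive values, and other members went both ways. All 8 tested JAZ genes, whose products repress jasmonate responses, had positive values. Over all genes JAZ9 rose, and adjusted over the list alone 5 of 15 members were higher: JAZ9, JAZ2 (0.73), JAZ6 (0.73), JAZ8 (0.79) and JAZ7 (0.85). The count over the list alone was 3 to 6 when 1 library was left out. The synthesis genes LOX2 (1.39), LOX3 (-0.73), LOX4 (-0.70) and AOS (-0.34) and the response genes VSP1 (-0.55) and VSP2 (0.94) did not pass. Camera called the list higher (adjusted p = 0.00349, adjusted p = 0.527 with an estimated correlation). The call was lost without wild type replicate 3 (adjusted p = 0.0658) and without mutant replicate 8 (0.0675).

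Of 8 tested TCP class II genes, which encode growth-regulating transcription factors of lateral organs, 7 had positive values (median 0.67). TCP17 (AT5G08070) had 0.47 ± 0.30 FPKM in wild type and 2.19 ± 0.71 in the mutant (log2 fold change 1.11, limma adjusted p = 0.114) and was the 1 member higher when adjusted over the list alone. TCP13 (0.64), TCP10 (0.82) and TCP4 (0.87) did not pass. Without mutant replicate 6, 7 of the 8 were higher by that measure (median 0.93, camera adjusted p = 1.73e-05). The list was called higher (camera adjusted p = 0.00165, adjusted p = 0.527 with an estimated correlation), and its libraries overlapped, with 1.81 to 2.71 log2 units in wild type and 2.33 to 3.45 in the mutant. With the touch list mean as a covariate the median was 0.12 and the call was lost (adjusted p = 0.563).

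Other hormone lists were not called by camera. Fry's test for change in either direction called auxin (adjusted p = 0.0203), cytokinin synthesis and breakdown (0.00522) and type-A response regulators (0.0203). It did not call gibberellin metabolism (0.609). Of 18 auxin genes, the kinase gene PID was lower when adjusted over the list alone (-0.92, 43.4 ± 12.8 against 22.0 ± 3.72 FPKM), and YUC6 (0.40) was not past it (camera adjusted p = 0.649). No auxin gene was lower without wild type replicate 2 or 4 or without mutant replicate 5 or 7, and 3 were without wild type replicate 3. Among 8 genes of cytokinin synthesis and breakdown, LOG4 (-0.65) and CKX6 (-0.66) were lower when adjusted over the list alone (camera adjusted p = 0.159). Only 1 was lower without wild type replicate 1, 2 or 4 or without mutant replicate 6, 7 or 8. Among 8 type-A response regulators of cytokinin signalling, ARR4 (-0.44) was lower by that measure and ARR8 (0.26) did not pass (camera adjusted p = 0.765). None was lower without mutant replicate 5, and 2 were without wild type replicate 3. None of the 4 gibberellin metabolism genes passed (camera adjusted p = 0.884; GA20OX2 had 0.51 and GA20OX1 -0.38); their median was -0.02 and their mean 0.02, with camera's direction up. No flavonoid and anthocyanin gene of 12 passed (camera adjusted p = 0.649; PAP2 had 0.80 and CHI -0.23), nor any of 12 clock genes (camera adjusted p = 0.107; RVE1 had 0.61 and LNK2 0.13). The clock list was called higher without wild type replicate 1 (adjusted p = 0.0296) and with the touch (0.00563) or photosynthesis (0.0475) list mean as a covariate. With an estimated correlation 0 of the 25 lists were called by camera, and 1, the ALOG family, had an unadjusted p under 0.05; by fry's test for change in either direction 10 were.

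The authors' deposited table lists 822 genes, 484 higher and 338 lower in the mutant. Of these, 732 were tested here and 90 fell below the FPKM minimum. All 732 had the same sign here as in the authors' deposited table, 712 had an unadjusted limma p under 0.05, and 33 passed after adjustment, which were all of the 33 genes called here. The libraries are the same, so this is not independent evidence. In the authors' deposited table CAL had a log2 fold change of -0.99 and AGL24 -0.99, and AGL6 1.16, BOP1 2.27, BOP2 1.27, TCP17 2.23 and SOC1 0.44. LSH3 was not in it. The authors' deposited table lists 10 touch, wounding and early stress genes as lower, such as ZAT12 (-3.40) and CBF2 (-4.04), and 0 as higher. For low genes the values here lay nearer to 0, because of the pseudocount of 1.

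**Figure D3:**
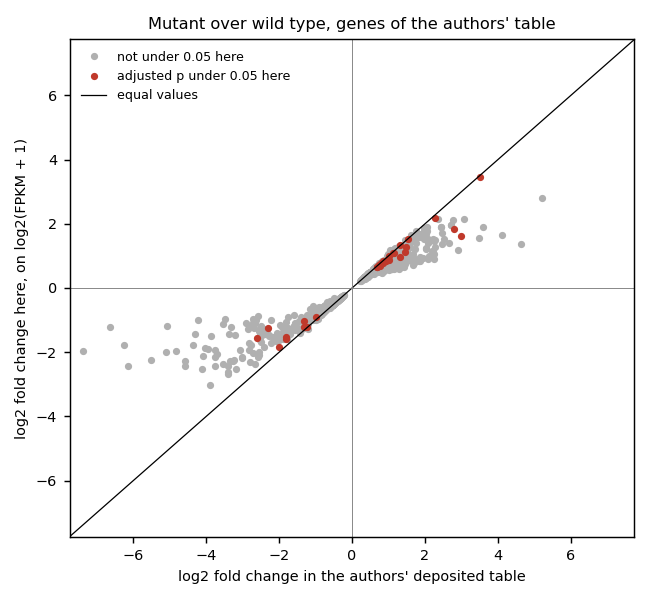
Log2 fold change of mutant over wild type in the authors' deposited table (horizontal axis) against the value here on log2(FPKM + 1) (vertical axis) for 732 genes; red points are the 33 genes with an adjusted p under 0.05 here and the line marks equal values. All points lie in the quadrants of equal sign, and many lie nearer to 0 on the vertical axis.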

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

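The tests of the touch list, of the photosynthesis and mitosis lists and of all 11 floral, boundary and meristem genes were chosen after the results were seen. The test of 9 of these genes was written before it was run, but its covariates were added after the data were seen. The test on other splits of the libraries was written before its result.

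Touch, wounding and early stress genes were lower in the mutant by a median log2 fold change of -1.96. Wild type replicate 1 alone is argued against, since without it the median was -1.25 and camera with the preset correlation still called the list (adjusted p = 2.59e-08; with all libraries, adjusted p = 0.527 with an estimated correlation). Handling that differed between libraries, whatever the genotype, stays open: the list mean ranged over 3.76 log2 units within wild type, more than the difference of 1.84 between the genotypes, and wild type replicate 4 lay within the mutant range. An effect of genotype also stays open, since the exact 2-sided permutation p was 0.0571 with overlapping libraries. A candidate explanation is therefore variable harvest stress in the wild-type libraries, with or without a genotype effect, and the labels give no harvest time or order that would separate them.

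Camera with the preset correlation called the photosynthesis list higher (median 0.46) and the G2 and mitosis list lower (median -0.18) in the mutant, both with adjusted p = 0.527 with an estimated correlation and with no member past the test over all genes. With genotype means removed, the 2 list means correlated negatively over the 8 libraries (Pearson r -0.742, one-sided within-group exact permutation p = 0.0226; Spearman -0.833, p = 0.0104), and r was -0.373 without the 2 libraries farthest from the median, so the relation rests largely on those. This correlation goes with a share of green or dividing tissue that varied between samples whatever the genotype. With the photosynthesis list mean as a covariate the median of the G2 and mitosis list went to -0.05 and its camera call was lost (adjusted p = 0.619). That covariate itself differed between genotypes (9.62 log2 units in wild type, 10.19 in the mutant). The covariate fit therefore cannot separate tissue share from a genotype effect on both lists. An overall loss of meristem tissue in the mutant also stays open: 88.9% of 18 shoot meristem and mitosis genes were negative, and the medians of photosynthesis (0.46), vascular (0.25), epidermis (0.14) and tapetum (0.05) markers were positive, the last from 2 genes. Of these 18 genes 10 were the G2 and mitosis list, and photosynthesis was among the markers, so the values largely restate the pattern. Of the 8 shoot meristem genes 6 were negative. A change of division rate in the mutant, a biological alternative, was not tested.

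In the floral transition, floral organ, organ boundary and shoot meristem lists, 11 genes passed when adjusted over the list alone, and CAL and AGL6 also over all genes. The test written before its own result covered 9 of them. It kept 106% of their mean absolute log2 fold change with the photosynthesis list mean in the fit and 93.5% with the touch list mean. It left out LOF1 and SPL15, and its genes were among those that passed in these same libraries. Both covariates also differed between genotypes: photosynthesis 9.62 in wild type and 10.19 in the mutant, touch 4.01 and 2.17. These fits therefore cannot separate a covariate from genotype, and the test excludes neither green tissue share nor handling stress. Over all 11 the means kept were 104% and 94.8% with every sign kept, but single genes shrank: with the photosynthesis mean LOF1 went from -0.42 to -0.18, SVP from -0.56 to -0.43 and BLR from -0.41 to -0.32 while BOP1 went from 1.29 to 1.61 and BOP2 from 1.09 to 1.48, and with the touch mean BOP2 went to 0.67 and SVP to -0.37 while SOC1 went from 0.43 to 0.63. None of the 11 passed over all genes in either fit: for CAL the log2 fold change went from -0.91 (SE 0.12) to -0.94 (SE 0.18) with the photosynthesis mean and -1.02 (SE 0.16) with the touch mean, and for AGL6 from 1.096 (SE 0.11) to 0.99 (SE 0.15) and 0.96 (SE 0.14). Green tissue share, handling stress and a genotype effect all stay open for these genes, although the fold changes of CAL and AGL6 stayed near their values. The share or stage of flowers in each sample was not tested. Within wild type, the floral organ identity list mean was lowest in replicate 1 (3.36) and highest in replicate 4 (4.46). The touch list mean was highest in replicate 1 (6.05) and lowest in replicate 4 (2.29), so that covariate may carry more than handling.

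Other splits of the 8 libraries into 4 and 4 number 35 with the real one. The real split called 33 genes and the highest other called 2, and 1 split, the real one, reached 33. The same held for the 24 increases and the 9 decreases (highest other 2). A share of 1 in 35 is the smallest this test can give. The other splits also mix the genotypes, which widens the spread within their groups. The result argues against chance for these counts but does not exclude it. For the 10 gene lists called by camera chance stays open: 7 of the 35 splits called as many, and the highest other called 13.

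Of 180 groups of 4 values tested, 10 held a library far from the other 3, where chance alone gives about 9. Wild type replicate 1 stood apart for HSP17.4 (5.16 FPKM against 0.83 to 0.89) and LSH10 (12.6 against 16.6 to 17.3). Wild type replicate 3 did so for APT3 (58.6 FPKM against 32.0 to 36.3), and wild type replicate 4 for BLR (45.4 against 34.6 to 35.0) and the early anther and meiosis list mean (2.70 against 2.44 to 2.45 log2 units). Mutant replicate 5 did so for ZAT12 (6.27 FPKM against 2.43 to 2.48), mutant replicate 7 for HA1 (193 against 230 to 235), and mutant replicate 8 for CDKB2;2 (34.8 against 36.2 to 36.3), HSP17.4 (1.06 against 0 to 0.06) and the heat shock list mean (2.41 against 2.91 to 2.99 log2 units).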

How the results depend on the processing

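The main counts were 24 increases, 9 decreases, 2 ALOG genes and 10 lists. They stayed within 1.5 times under pseudocounts of 0.1 and 0.5, a mean FPKM of 5, median-of-ratios and quantile scaling and robust moderation, and no scaling moved the median log2 fold change by more than 0.02. With no filter there were 7 increases, 5 decreases and 1 ALOG gene, after TPM rescaling 14 and 5, at an adjusted p under 0.01 2 and 2, and 10 increases had an absolute log2 fold change of 1 or more. Library weights gave 1265 increases, 1058 decreases and 6 lists, with weights of 4.55 for wild type replicate 2 and 4.38 for mutant replicate 7 against 0.29 to 0.96 for the others; under such weights 3 of the 35 splits, the real one included, called as many as the real 2323, and the highest other called 5228. Leaving out 1 library gave 0 to 79 increases, 0 to 25 decreases, 0 to 2 ALOG genes and 6 to 10 lists. The lowest gene counts came without wild type replicate 2, the highest without wild type replicate 3 and the fewest lists without mutant replicate 8; fewer samples enter these fits. With an estimated correlation camera called 0 lists, and fry called 1. Of the authors' genes 712 passed at an unadjusted p under 0.05. Added after the data were seen, a threshold of 0.10 gave 77 and 35. The touch list mean as a covariate left 0 increases, 1 decrease and 0 ALOG genes (limma; 1095 higher and 785 lower at an unadjusted p under 0.05), and, of the lists called without it, turned floral organ identity (median -0.44) and heat shock (0.60); it also made camera call organ boundary, floral transition, MCM and clock, and turned medians of lists not called, such as salicylate (0.11) and epidermis (-0.16). The photosynthesis list mean left 0, 0 and 0 (596 and 449) and, of the called lists, turned the vascular list (-0.0024) and, by construction, the photosynthesis list itself (-0.02); it also made camera call organ polarity (adjusted p = 0.0118) and clock (0.0475), and turned medians of lists not called, such as organ boundary (0.04) and floral transition (0.04). Unless stated, the cause was not tested. No paired analysis was possible because the genotypes share no replicate number. Unknown depth limits what can be said of genes near 0.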

Other observations

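The 4 lists below and the tests on them were chosen after the authors' deposited table was seen. That table came from the same libraries. The counts and the camera and permutation p-values of these lists are therefore descriptive and not independent evidence. The test on gene neighbours was written before its result.

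Most genes of cuticular wax synthesis were higher in the mutant when adjusted over the list alone. By that measure 12 of 16 were higher and 4 did not pass, and 15 had positive values (median 0.43). They included the fatty acid elongase gene KCS6 (0.46), the acyl-CoA synthetase gene LACS1 (0.64), CER2 (0.68) and the alkane-forming CER1 (0.49) and CER3 (0.58), and none passed over all genes. Camera with the preset correlation called the list (adjusted p = 7.73e-10 over all 29 lists), but not with an estimated correlation (adjusted p = 0.148 over all 29). Each mutant library (6.74 to 6.97 log2 units) lay above each wild-type library (6.33 to 6.64), with an exact 2-sided permutation p of 0.0286, the smallest that 4 against 4 allow. Of the 16 wax genes, 10 were listed as higher in the authors' deposited table and 0 as lower. The choice of the list therefore favoured small p-values in both tests. These genes act in the epidermis, whose 5 fixed markers had a median of 0.14.

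Some genes of sulfate uptake and assimilation were higher. Besides SULTR2;1, which passed over all genes, 6 others of the 17 tested were higher when adjusted over the list alone, among them APR1 (1.07), LSU1 (1.57) and SDI1 (1.78), and 10 did not pass. Camera with the preset correlation called the list (adjusted p = 1.49e-08 over all 29 lists), but not with an estimated correlation (adjusted p = 0.148), and the libraries of both genotypes overlapped (3.67 to 4.30 log2 units in wild type, 4.28 to 4.66 in the mutant; exact 2-sided permutation p = 0.0571). Of 18 abscisic acid response genes, 5 were higher when adjusted over the list alone, among them HB7 (1.60) and RD22 (0.72), with a camera adjusted p = 0.00120 and adjusted p = 0.453 with an estimated correlation, over all 29 lists. Of 14 nitrate genes, 4 were higher, namely NRT1.5, CLC-B (0.96), GLN1;4 (1.19) and NRT1.1 (1.43), and 2 were lower, LBD39 (-1.34) and BT5 (-1.997), by the same measure (camera adjusted p = 0.145).

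Some regulators below the FPKM minimum appear in the authors' deposited table and were picked out after their values were seen. In the authors' deposited table TCP5 (2.07), TCP12 (2.48), TCP18 (2.68) and AGL72 (3.68) were higher in the mutant, as was AGL71 (2.22), which was above the minimum. Their mean levels here were 0.84, 0.15, 0.36, 0.59 and 3.67 FPKM.

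Sequence differences linked to the mutated loci were considered as a source of calls. Of 300 tested genes within 50 gene positions of LSH1, LSH3 or LSH4, 4.33% were in the authors' deposited table, against 4.13% of 17366 others (2-sided Fisher exact p = 0.771). The share is higher by less than its counting error, so an effect of linkage on a few neighbours cannot be told apart from none with 13 listed neighbours. By AGI code the called decrease ERF15 (AT2G31230) lies near LSH3 (AT2G31160). A local effect of the mutated locus on ERF15 was not tested.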
